A study of Mus musculus with 249 samples.

How the data were processed

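Mouse 3T3-L1 cells were profiled by single cell RNA barcoding and sequencing applied to lysates of wells, a method that reads the 3' ends of transcripts. Per the labels' protocols, 50000 cells per well were plated in 24-well plates and grown for 4 days, and wells other than the naive ones then received induction medium with vehicle (0.2% DMSO) or a test chemical, with fresh doses on days 3, 5 and 7. Per the labels' protocols the RNA was brought to 5 ng/ul, and the reads carried a barcode of 6 bases, a molecular identifier of 10 bases and 46 bases of cDNA. Reads were aligned with BWA 0.7.10 to GRCm38, per the submitters' processing notes. The deposited values are counts, whole numbers per gene symbol for 21511 symbols in each of 249 files, and they were not normalized. Whether each count is a molecule or a read is not given in the sources used here, so the floors below cover counting error only, while the 95% intervals of log2 fold changes come from the fit and take in the spread between wells. Of the symbols 20435 (95%) were found by name in GENCODE M21, and none of the 13 protein genes of the mitochondrial genome was among the symbols. The labels do not say that wells were separate cultures, so the p-values measure the spread between wells. In the main fit that spread was estimated for each gene over all groups together, and not from the wells of a single chemical.

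Libraries were grouped by the chemical in the labels, and replicates were numbered within a chemical by plate and well, since the labels give no replicate numbers. The 249 libraries formed 78 groups on 6 plates. A chemical with 1 library (T0901317) was left out of the tests and is described in the closing section. Total counts had a median of 195890 (13048 to 2273411) and 32 libraries lay under 48972.5, 0.25 of the median. The tests, samples, covariates, gene lists, the genes to be named and most alternatives were chosen before the data were examined. The alternatives without plate 6, without a block of wells of plate 5 and with only that block for 2 chemicals, each pair of libraries left out for chemicals with 4, and other sizes of the call count in the screen, were chosen after the data were seen.

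The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and robust estimation, on the 8938 genes that passed filterByExpr (minimum count 10, total 15). A single model with 1 term per group and 1 per plate (82 coefficients) was fitted to 248 libraries, and each comparison was a contrast of it, with chemicals of a class weighted equally. The common dispersion was 0.0959, the trended dispersion ran from 0.0765 to 0.176 and the normalization factors from 0.606 to 1.93. P-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. The fits were run through a solver written with Rcpp 1.1.0, with version 1.17.8 of data.table for reading files. On 60 genes and 3 contrasts it differed from edgeR by at most 5.49e-07 in deviance, and the code that takes the contrasts of the DESeq2 1.42.0 fit was checked against that tool on 8936 genes. Log2 fold changes are printed with their standard error from the fit (±), and group means with SD in TMM-scaled CPM. The standard error thus rests on the spread over all groups, and the SD on the libraries of the group. Folds are adjusted for plate and means are not. A gene with no count in a group is given as at least so many times lower, from a floor of 3 counts over the group.

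Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, lists with at least 5 tested members), with a preset correlation of 0.01 between genes and again with the correlation estimated from the data. P-values were adjusted over all lists and comparisons, 325 tests for the 13 main comparisons. Beside each list stands the number of members called in the gene test over all genes and with p adjusted over the list alone. The fatty acid oxidation list also holds the lipase inhibitor Angptl4 and the fatty acid carrier Fabp3. Genes named are the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 4, up to 4 members by smallest p of a list called under both correlations, and a fixed panel; the limit to lists called under both correlations was set after the data were seen. For single chemicals and pairs they are the panel and the 4 genes with the smallest p. Pairs are given with a 95% interval.

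The model was tested on simulated counts for the 8938 genes with 200 of them changed. Of the genes changed 4-fold it called 99% in the naive comparison, 65% for the thiazolidinediones, 92% for T0070907, 85% for the organotins, 72% for LG100268 and 49% for rosiglitazone, and of those changed 2-fold 69%, 11%, 25%, 32%, 14% and 3%. False calls were 8 of 176, 51 of 127, 7 of 124, 15 of 132, 2 of 88 and 2 of 54 in the same order. These rates hold for simulated counts, and the splits and vehicle draws described below were made on the real libraries. For PCB 126 no gene was changed in the simulation and 0 were called. Alternatives were DESeq2 size factors in edgeR, the DESeq2 Wald test, no filter, a stricter filter (mean count 5), no plate term, only the groups compared, no libraries under 0.25 of the median total, each chemical of a class left out, and each replicate left out. Leaving out replicate 1, for instance, removed that replicate of every chemical at once and kept vehicle and naive libraries, and where 1 library was left in a group it was assumed to vary like the other groups. Counts of genes were also compared with 100 other splits of the same libraries over all plates and again within plates (fewer where fewer exist), the latter chosen after the data were seen, and 100 draws each of 2, 3 and 4 vehicle libraries were tested as if they were a chemical.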

Results

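The data comprised 249 libraries of mouse 3T3-L1 cells, a fibroblast line that turns into fat cells when given a hormone cocktail. After 4 days of growth the cells were induced with 250 nM dexamethasone, 167 nM insulin and 0.5 mM IBMX, and they were dosed again with a test chemical or vehicle on days 3, 5 and 7. Induced vehicle cultures in 0.2% DMSO had 25 libraries, cultures kept in maintenance medium without induction (naive cells) had 15, and 76 chemicals had 209 between them. By chemical, 1 was sequenced in 1 library, 28 in 2, 36 in 3 and 11 in 4. Doses were not given in the sources used here. Total counts ran from 13048 to 2273411 per library with a median of 195890, and a median of 8850 genes was detected. In 32 libraries the total lay under 48972.5, 0.25 of the median. Adipoq (adiponectin, chromosome 16, 23146536 to 23158028), Fabp4 (a fatty acid carrier, chromosome 3, 10204088 to 10208576) and Pparg (the master regulator of fat cells, chromosome 6, 115360951 to 115490399) lay at these GRCm38 positions in GENCODE M21.

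Transcripts of 12 neutrophil granule genes, among them S100a8, Camp and Mpo, took a median of 0.00415%, 0.00842%, 0.00736% and 0.00606% of the counts on plates 1 to 4, 0.101% on plate 5 and 5.82% on plate 6, where the highest library reached 15.7%. Neutrophils are blood cells and these genes were counted as markers of another cell type. Plate 6 held 17 libraries, of which 2 were vehicle and 1 was naive. Of 607 pairs of libraries from one group, 0 were identical, and the median chi-square per degree of freedom between them was 4.33. The 2 troglitazone libraries (0.992 over 513 genes) and the 2 MCC-555 libraries (1.07 over 456 genes) differed by about the sampling noise at their low totals. On plate 5, replicates 1 and 2 of roscovitine (1.14), resolvin-E1 (1.15) and T0070907 (1.29) were far closer than the other pairs of those chemicals, of which the closest reached 1.72. Some pairs of other groups were as close, such as vehicle replicates 15 and 16 (1.12).

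**Figure D1:**
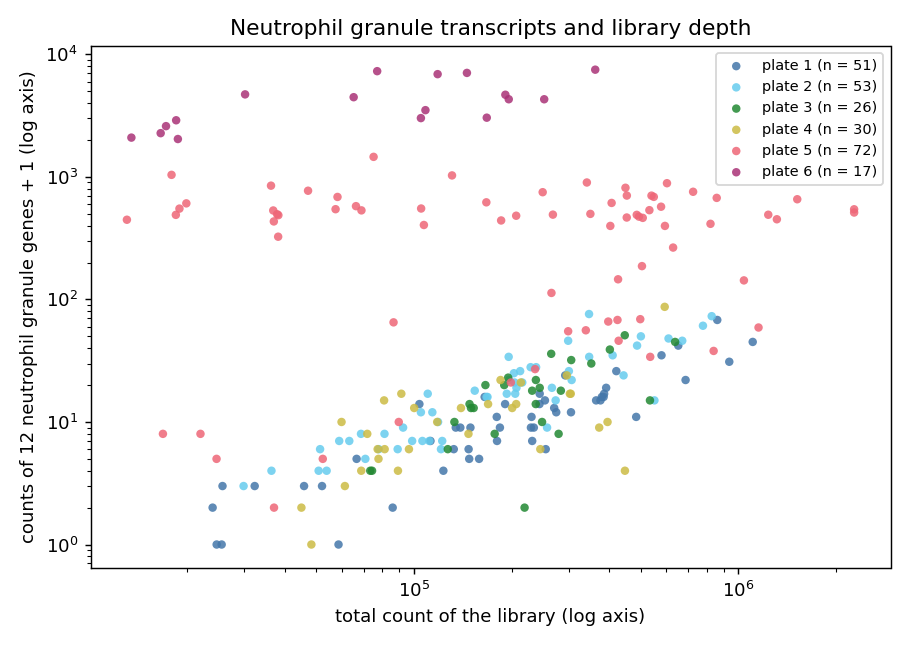
Total count of each library (log axis) against its counts of 12 neutrophil granule genes plus 1 (log axis), coloured by plate, 1 point per library. Median counts of these genes were 483.5 on plate 5 (72 libraries) and 4299 on plate 6 (17 libraries), against 9 to 16 on plates 1 to 4.

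The first comparison asked what induction changed, together with the vehicle, which the naive wells did not receive. Naive cells held far less of the fat cell transcripts than induced vehicle cells. Adiponectin (Adipoq) lay at 84.2 ± 114 CPM (SD, n = 15) against 2901 ± 3891 (n = 25), a log2 fold change of -5.06 ± 0.29 (SE), and Car3, a carbonic anhydrase abundant in fat, at -5.74 ± 0.35. The fatty acid carriers Fabp4 (-4.48 ± 0.29) and Cd36 (-4.44 ± 0.37) fell, as did Pparg (-2.26 ± 0.28). The thyrotropin receptor Tshr had no count in the naive libraries and was at least 35.5-fold lower, with a floor of 3 counts over the group. Of 23 fat cell genes, 22 fell over all genes and 23 when adjusted over the list alone (adjusted p = 1.44e-152, and adjusted p = 3.19e-13 with an estimated correlation). Lipid synthesis fell as a list, with 10 of 19 genes lower over all genes and as many adjusted over the list alone (adjusted p = 4.22e-15, and adjusted p = 0.0108 with an estimated correlation), including Thrsp (-4.39 ± 0.48) and the desaturase Scd1 (-3.00 ± 0.33).

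The collagenase Mmp13 (2.60 ± 0.37), the methyltransferase Inmt (2.46 ± 0.30) and the matrix protein Mfap4 (1.74 ± 0.16) were higher in naive cells. Among 19 extracellular matrix genes, 5 rose and 1 fell over all genes, and 13 rose and 1 fell when adjusted over the list alone. That list's call (adjusted p = 2.99e-07) was lost under the other correlation (adjusted p = 0.127 with an estimated correlation). The edgeR test called 414 of 8938 genes, 154 higher and 260 lower. Within single plates, with fewer libraries, the fit called 38 genes on plate 1, 178 on plate 2, 225 on plate 4 and 30 on plate 5. Plate 3 held no naive library and plate 6 a single one.

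**Figure D2:**
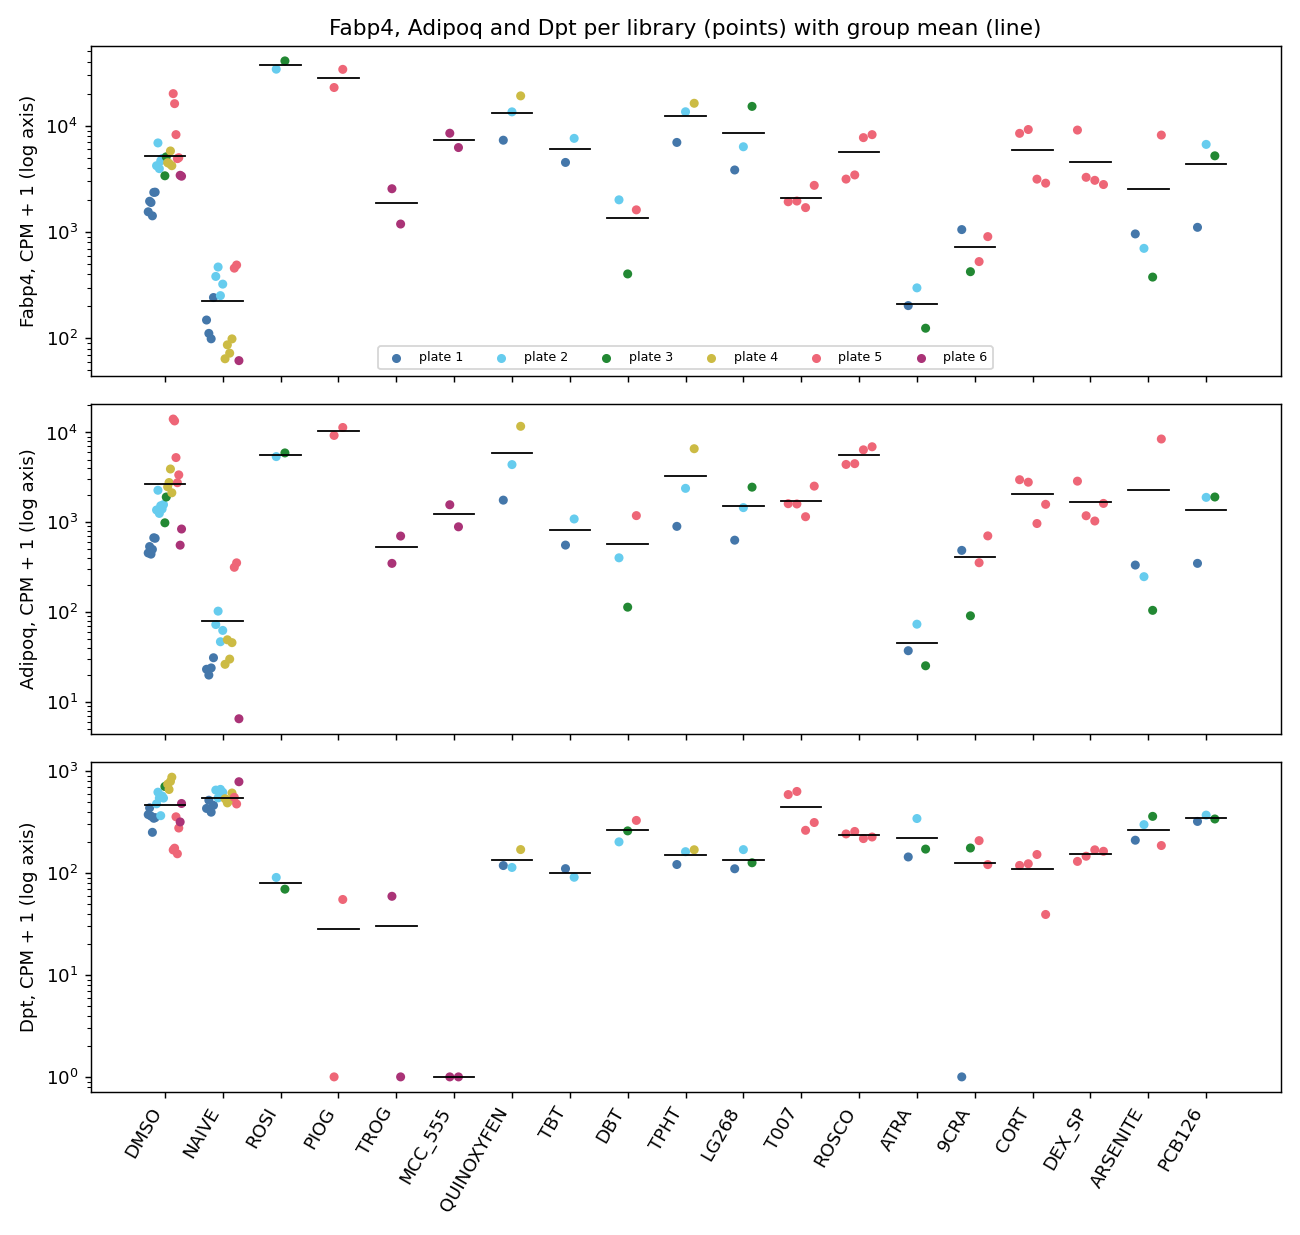
CPM plus 1 (log axis) of Fabp4, Adipoq and the matrix gene Dpt in each library of 19 groups, coloured by plate, with a line at the group mean; CPM were taken from the raw totals. Values spread widely within a group, as in vehicle Adipoq with an SD of 3891 CPM around a mean of 2901 on the TMM-scaled values.

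Thiazolidinediones, drugs that activate the receptor PPARgamma, were tested next. In rosiglitazone, whose 2 libraries were deep (219311 to 257241 counts), PPARgamma target genes rose. Fabp4 rose by 2.90 ± 0.63 (SE), Cd36 by 2.41 ± 0.57, the lipid droplet gene Cidec by 3.60 ± 0.62, the lipase inhibitor Angptl4 by 2.32 ± 0.35, the epoxide hydrolase Ephx2 by 3.63 ± 0.41 and the respiratory subunit Cox7a1 by 4.62 ± 0.61, on the log2 scale. Of 21 PPARgamma target genes 17 rose over all genes and 19 adjusted over the list alone (adjusted p = 5.16e-39, and adjusted p = 5.86e-06 with an estimated correlation). The fatty acid oxidation list, which includes Angptl4, rose too. Of its 24 genes 17 were higher under both adjustments, over all genes and adjusted over the list alone (adjusted p = 1.78e-21, and adjusted p = 0.00277 with an estimated correlation). Of 19 matrix genes 8 fell over all genes and 15 adjusted over the list alone (adjusted p = 3.71e-15, and adjusted p = 0.0183 with an estimated correlation). Without the plate term Cidec stood at 1.21, adjusted p = 0.65. The Adipoq rise of 1.90 ± 0.58 was no longer called without replicate 2 (1.57, adjusted p = 0.407).

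Averaged over rosiglitazone, pioglitazone, troglitazone and MCC-555 (8 libraries), matrix genes were lower than in vehicle. Decorin (Dcn) fell by 3.73 on the log2 scale (SE 0.33), from 3711 ± 1066 CPM (SD, n = 25) to 411 ± 456 (n = 8). Periostin (Postn, -3.61 ± 0.45), Col3a1 (-3.23 ± 0.35) and Sparc (-2.63 ± 0.29) fell with it. Of 19 matrix genes, 14 fell over all genes and 17 when adjusted over the list alone (adjusted p = 9.53e-25, and adjusted p = 0.000446 with an estimated correlation). Dcn, Postn and Col3a1 stayed called in each alternative tried, while Sparc was lost without the shallow libraries (-0.72, adjusted p = 0.161), a fit that left rosiglitazone as the only member. Fabp4 (0.76 ± 0.42, adjusted p = 0.2), Adipoq (0.21 ± 0.42, adjusted p = 0.75) and Cidec (1.56 ± 0.60, adjusted p = 0.0803) did not pass for the class. Neutrophil transcripts took 15.1% to 15.7% of the counts in troglitazone, 13.7% to 15.5% in MCC-555 and 0.0027% to 5.8% in pioglitazone, against 0.000456% to 0.00311% in rosiglitazone and 0.00116% to 4.84% in vehicle.

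edgeR called 1428 (13 higher and 1415 lower) genes for the class, 467 without replicate 1 and 603 without replicate 2 of each. The libraries of the other 3 chemicals were shallow (17909 to 37059 for pioglitazone, 17221 to 18505 for troglitazone, 13469 to 16580 for MCC-555), and the median log2 fold change of all genes was -1.33. With DESeq2 size factors that median moved by 0.71, and 339 (157 higher and 182 lower) genes were called, so that 46.3% of the calls were higher in place of 0.91%. Without the shallow libraries, which left rosiglitazone as the only member, 545 (403 higher and 142 lower) were called, and without plate 6 363 (120 higher and 243 lower). On simulated data of this design 51 of 127 calls were false (40.2%), all 51 in the lower direction. The lists for fat cells (adjusted p = 0.000731, adjusted p = 0.5 with an estimated correlation), PPARgamma targets (adjusted p = 2.04e-06, adjusted p = 0.147 with an estimated correlation), brite fat (adjusted p = 0.0151), fatty acid oxidation (adjusted p = 0.00992), lipid synthesis (adjusted p = 0.0324) and cholesterol synthesis (adjusted p = 0.00404) had negative medians and means although the test, which compares a list with the other genes, gave them as higher. For the cell cycle (adjusted p = 6.28e-05) and hypoxia (adjusted p = 0.00644) lists the mean was negative and the median positive. The last 6 calls were also lost with an estimated correlation (adjusted p = 0.192, 0.469, 0.572, 0.439, 0.209 and 0.383).

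Set against the thiazolidinediones, the organotins and quinoxyfen both held more matrix transcript. Postn was higher by 3.02 ± 0.48 and Dcn by 2.88 ± 0.38 in the organotins, and by 2.88 ± 0.53 and 2.47 ± 0.45 in quinoxyfen. Of 19 matrix genes 11 were higher in the organotins over all genes and 15 adjusted over the list alone (adjusted p = 9.63e-17, and adjusted p = 0.00572 with an estimated correlation), and 10 and 14 in quinoxyfen (adjusted p = 4.24e-13, and adjusted p = 0.0185 with an estimated correlation). Macrophage markers were lower in quinoxyfen as a list with 0 of 12 members called (adjusted p = 8.9e-08, and adjusted p = 0.0253 with an estimated correlation). Both comparisons share the shallow libraries and the neutrophil share of the thiazolidinediones given above. They called 693 (684 higher and 9 lower) and 778 (772 higher and 6 lower) genes, with 70 (41 higher and 29 lower) and 31 (29 higher and 2 lower) without plate 6. Without the shallow libraries, which left rosiglitazone as the only thiazolidinedione, the balance turned, to 253 (23 higher and 230 lower) and 18 (4 higher and 14 lower), of which 24 and 5 were among the first calls. The counts fell to 119 and 127 without replicate 1 and to 185 and 275 without replicate 2. Without plate 6 Dcn in quinoxyfen stood at 1.27, adjusted p = 0.172 and Postn at 1.21, adjusted p = 0.141, and without the shallow libraries Dcn in the organotins at 1.08, adjusted p = 0.161. With DESeq2 size factors, which moved the median of all genes by -0.72 and -0.63, 158 (99 higher and 59 lower) and 107 (85 higher and 22 lower) were called, 62.7% and 79.4% of them higher in place of 98.7% and 99.2%. For PPARgamma targets, the cell cycle and hypoxia in the organotins and for interferon and hypoxia in quinoxyfen, the test gave a lower list although its median, its mean or both were positive. These calls were lost with an estimated correlation (adjusted p = 0.505, 0.439 and 0.464 in the organotins and 0.242 and 0.325 in quinoxyfen).

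Quinoxyfen, a fungicide, raised fat cell genes above the level of induced vehicle cells. The fatty acid transporter Cd36 rose by 2.21 ± 0.47 (SE) on the log2 scale, from 335 ± 378 CPM (SD, n = 25) to 1047 ± 478 (n = 3). Angiotensinogen (Agt) rose by 2.16 ± 0.32 and the lipoprotein receptor Scarb1 by 2.17 ± 0.41, and the matrix gene Dpt fell (-1.89 ± 0.31). Of 23 fat cell genes 9 rose over all genes and 20 when adjusted over the list alone (adjusted p = 7.54e-34, and adjusted p = 0.00194 with an estimated correlation). Of 22 cholesterol synthesis genes 6 rose, and 17 adjusted over the list alone (adjusted p = 8.19e-20, and adjusted p = 0.00194 with an estimated correlation), including the synthase Hmgcs1 (1.68 ± 0.33) and Insig1 (2.02 ± 0.41). Of 16 interferon response genes 2 fell, and 5 adjusted over the list alone (adjusted p = 1.1e-07, and adjusted p = 0.0141 with an estimated correlation), with Oasl2 at -4.16 ± 1.68. Matrix genes fell as a list with 1 of 19 called and 5 adjusted over the list alone (adjusted p = 6.49e-14, and adjusted p = 0.0141 with an estimated correlation).

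edgeR called 75 (64 higher and 11 lower) genes for quinoxyfen. Without replicate 3, Hmgcs1 (1.11, adjusted p = 0.305) and Insig1 (1.66, adjusted p = 0.188) were no longer called, and without replicate 1 neither was Oasl2 (-4.59, adjusted p = 0.118). Without replicates 1, 2 and 3 the count was 64, 31 and 20. Folds are adjusted for plate while group means are not: Cidec rose by 2.18 ± 0.52 although its mean lay at 492 CPM against 637 in vehicle, and without the plate term its fold was -0.36. Cd36 was not called without the plate term (1.62, adjusted p = 0.281).

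LG100268, a ligand of the retinoid X receptor, raised the fatty acid oxidation and citric acid cycle lists. Inmt rose by 5.05 ± 0.45 (SE) on the log2 scale, from 22.9 ± 25 CPM (SD, n = 25) to 498 ± 297 (n = 3). The heart-type fatty acid carrier Fabp3 (5.59 ± 0.96), Cox7a1 (4.06 ± 0.54), Ephx2 (2.53 ± 0.38), Agt (2.36 ± 0.33) and Angptl4 (1.78 ± 0.30) rose as well. Fabp3 and Angptl4 are also members of the fatty acid oxidation list. Of 24 fatty acid oxidation genes 5 rose over all genes and 8 when adjusted over the list alone (adjusted p = 3.03e-21, and adjusted p = 0.00105 with an estimated correlation), and of 17 citric acid cycle genes 1 and 9 (adjusted p = 6.1e-13, and adjusted p = 0.0225 with an estimated correlation). Nuclear genes of the respiratory chain were higher as a list, 1 of 38 over all genes and 20 adjusted over the list alone (adjusted p = 1.57e-27), a call lost under the other correlation (adjusted p = 0.0507 with an estimated correlation). Fabp4 (0.99 ± 0.52, adjusted p = 0.661) and Adipoq (0.28 ± 0.48, adjusted p = 0.99) did not pass. edgeR called 34 (27 higher and 7 lower) genes, and 7 without replicate 3, 28 without replicate 1 and 26 without replicate 2. The oxidation genes Acaa2 (1.22, adjusted p = 0.276) and Hadhb (1.01, adjusted p = 0.933) were not called without replicate 3.

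The organotins tributyltin, dibutyltin and triphenyltin were tested as a class (8 libraries), in which Angptl4 stood 1.59 ± 0.22 (SE) higher on the log2 scale, at 453 ± 295 CPM (SD, n = 8) against 139.8 ± 46.6 (n = 25). Among the members Angptl4 rose in tributyltin (2.34 ± 0.36) and triphenyltin (2.26 ± 0.30) but not past the test in dibutyltin (0.17 ± 0.38, adjusted p = 0.989). In the class Agt rose by 1.41 ± 0.26, and the fat cell protease Cfd (-2.52 ± 0.40), the matrix gene Dpt (-1.56 ± 0.23) and the transcription factor Zeb2 (-1.77 ± 0.40) fell. Of 24 fatty acid oxidation genes 3 rose over all genes and 5 when adjusted over the list alone (adjusted p = 2.06e-16, and adjusted p = 0.00561 with an estimated correlation). That list includes Angptl4. Matrix genes were lower as a list, 2 of 19 over all genes and 12 adjusted over the list alone (adjusted p = 5.26e-08), a call lost under the other correlation (adjusted p = 0.0957 with an estimated correlation). Fabp4 (-0.10 ± 0.35, adjusted p = 0.979) and Adipoq (-0.86 ± 0.34, adjusted p = 0.394) did not pass for the class. In dibutyltin (n = 3) Adipoq fell by 2.94 ± 0.54 (adjusted p = 0.021), a call lost without each of its libraries (-3.30, adjusted p = 0.0588, -2.75, adjusted p = 0.642 and -3.13, adjusted p = 0.224 without replicates 1, 2 and 3) and without the plate term (-2.48, adjusted p = 0.869). Fabp4 (-2.53 ± 0.54, adjusted p = 0.104) and Cd36 (-2.57 ± 0.71, adjusted p = 0.152) did not pass there with edgeR, but did with DESeq2 (adjusted p = 5.6e-05 and 0.00453) and without a filter (adjusted p = 1.33e-05 and 0.000129). Fabp4 also passed with DESeq2 size factors (adjusted p = 0.0336). Tributyltin (n = 2) stood at 0.75 ± 0.62 for Fabp4 and -0.36 ± 0.59 for Adipoq (adjusted p = 1 for both). Its Cd36 (1.79 ± 0.58, adjusted p = 0.247) and Cidec (1.76 ± 0.67, adjusted p = 0.693) passed only without a filter (adjusted p = 0.000715 and 0.0207). In triphenyltin (n = 3) Cd36 (2.49 ± 0.48) and Cidec (2.40 ± 0.55) rose, Cidec not without replicate 3 (2.17, adjusted p = 0.169) or without the plate term (-0.051, adjusted p = 1). Fabp4 there (1.47 ± 0.52, adjusted p = 0.154) passed with DESeq2 (adjusted p = 0.0066), DESeq2 size factors (adjusted p = 0.00738) and no filter (adjusted p = 0.00124), and Adipoq (0.71 ± 0.48, adjusted p = 0.743) did not pass. PPARgamma target and brite fat genes were higher by the test with a negative median (adjusted p = 0.147 with an estimated correlation and adjusted p = 0.249 with an estimated correlation), and for the heat shock and metal list (adjusted p = 0.0495, adjusted p = 0.488 with an estimated correlation) the mean was negative and the median positive. The neutrophil share in dibutyltin was 0.00363% to 1.18%.

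edgeR called 18 (5 higher and 13 lower) genes for the organotins, 23 with DESeq2 size factors (60.9% of them higher in place of 27.8%) and 5 (1 higher and 4 lower), 11 (2 higher and 9 lower) and 63 (51 higher and 12 lower) without triphenyltin, tributyltin and dibutyltin. On simulated data of this design 15 of 132 calls were false, all 15 in the lower direction. Agt was not called without replicate 3 (1.01, adjusted p = 0.278) or without triphenyltin (0.76, adjusted p = 0.593), and Zeb2 was not without tributyltin (-1.40, adjusted p = 0.0886). Without replicates 1, 2 and 3 of each chemical 6, 10 and 7 genes were called.

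Fat cell genes were lower in T0070907, an antagonist of PPARgamma. Fabp4 fell by 2.29 on the log2 scale (SE 0.49), with 1914 ± 779 CPM (SD, n = 4) against 5652 ± 4797 (n = 25). Adipoq (-2.27 ± 0.45), Cidec (-2.23 ± 0.49) and Pparg (-1.55 ± 0.41) were lower, and so were the acute phase gene Orm1 (-3.29 ± 0.53) and the brite fat gene Cox8b (-3.24 ± 0.61). Of 23 fat cell genes 13 fell over all genes and 20 when adjusted over the list alone (adjusted p = 7.44e-14), a call lost under the other correlation (adjusted p = 0.0862 with an estimated correlation). Of 38 respiratory chain genes 22 fell, and 28 adjusted over the list alone (adjusted p = 2.33e-24, adjusted p = 0.0762 with an estimated correlation). Of 19 matrix genes 10 rose, and 11 adjusted over the list alone (adjusted p = 0.00644, adjusted p = 0.464 with an estimated correlation). Arid1a, a chromatin remodelling gene (2.14 ± 0.45), and Bcl9l, a Wnt pathway coactivator (2.48 ± 0.71), were among the 8 largest rises.

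The neutrophil genes Mpo (-4.67 ± 1.75), Chi3l3 (-3.93 ± 1.26), S100a8 (-3.39 ± 0.82) and Camp (-3.33 ± 0.75) were lower too, and macrophage markers fell as a list, 2 of 12 over all genes and 5 adjusted over the list alone (adjusted p = 2.3e-07, and adjusted p = 0.033 with an estimated correlation). Over the 72 libraries of plate 5 neutrophil counts did not rise with the remaining counts (Spearman correlation 0.0428). Deep libraries there thus tend to hold a lower neutrophil CPM. Since T0070907 replicates 1 and 2 were deep, the neutrophil falls cannot be told apart from an effect of depth, and the macrophage list was not tested for it. The neutrophil share was 0.01% to 0.101% in the 4 T0070907 libraries, which all lay on plate 5, and none of these neutrophil genes was called without replicate 1 (Mpo -3.91, adjusted p = 0.174, Camp -3.18, adjusted p = 0.0545) or without replicate 2 (S100a8 -3.21, adjusted p = 0.117, Chi3l3 -3.72, adjusted p = 0.22). Pparg was not called without replicate 2 (-1.53, adjusted p = 0.0694). edgeR called 1318 (831 higher and 487 lower) genes, 226 without replicate 1, 145 without replicate 2 and 2839 without replicate 3. Replicates 1 and 2 lay in a block of 8 wells of plate 5 with deep libraries, and without that block 0 genes were called by edgeR (648 at an unadjusted p under 0.05, with DESeq2 not run there). Fabp4 then stood at -1.86, adjusted p = 0.539, Adipoq at -1.84, adjusted p = 0.452 and Arid1a at 1.06, adjusted p = 0.8. Without the plate term Fabp4 (-1.57, adjusted p = 0.0662), Adipoq (-0.89, adjusted p = 0.387) and Cidec (-0.40, adjusted p = 0.796) were not called. With DESeq2 size factors the median of all genes moved by 0.93, 4712 (4517 higher and 195 lower) genes were called, 95.9% of them higher in place of 63.1%, and Pparg was lost (-0.79, adjusted p = 0.0757).

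In roscovitine, an inhibitor of cyclin-dependent kinases, many genes differed from vehicle, but 0 were called without the well block of plate 5. The fat cell list was not called (adjusted p = 0.203, with 1 member higher and 2 lower over all genes, and 3 and 2 adjusted over the list alone). Bcl9l rose by 3.40 ± 0.70 (SE) on the log2 scale, from 3.83 ± 5.71 CPM (SD, n = 25) to 33.5 ± 30.9 (n = 4), and Phrf1 by 2.63 ± 0.59. The collagen gene Col27a1 (2.47 ± 0.52) and Arid1a (2.36 ± 0.46) rose as well, and the carbonic anhydrase Car2 (-2.97 ± 0.92) and Sncg (-2.63 ± 0.56) fell. Fabp4 (-0.62 ± 0.49, adjusted p = 0.434) and Adipoq (-0.43 ± 0.45, adjusted p = 0.565) did not pass. Of 29 cell cycle genes 1 fell under both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.00559, adjusted p = 0.419 with an estimated correlation). Of 15 genes picked as targets of CDK5 acting on PPARgamma, 2 rose and 2 fell (adjusted p = 0.414), with 2 and 2 adjusted over the list alone. edgeR called 813 (701 higher and 112 lower) genes, 41 without replicate 1 and 9 without replicate 2, the libraries in the well block of plate 5, 1893 without replicate 3 and 2075 without replicate 4, and 0 without that block (604 at an unadjusted p under 0.05, with DESeq2 not run there). Without replicate 2 the calls of Col27a1 (2.37, adjusted p = 0.0858), Arid1a (2.06, adjusted p = 0.0858), Car2 (-2.49, adjusted p = 0.222) and Sncg (-2.53, adjusted p = 0.0827) were lost. Phrf1 and Bcl9l kept their call without either replicate alone and lost it without the block (1.49, adjusted p = 0.899 for Phrf1). With DESeq2 size factors the median of all genes moved by 0.95 and 4302 (4169 higher and 133 lower) genes were called, 96.9% of them higher in place of 86.2%.

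The retinoic acids, all-trans and 9-cis, lowered fat cell genes. Adipoq fell by 4.20 on the log2 scale (SE 0.39), from 2901 ± 3891 CPM (SD, n = 25) to 248 ± 268 (n = 7), with Fabp4 at -3.85 ± 0.39, Cidec at -4.25 ± 0.73 and Pparg at -2.29 ± 0.41. The retinoic acid hydroxylase Cyp26b1 (4.15 ± 0.51), the retinaldehyde reductase Dhrs3 (2.53 ± 0.24) and Inmt (5.82 ± 0.35) rose. Of 23 fat cell genes 22 fell over all genes and 23 when adjusted over the list alone (adjusted p = 1.53e-64, and adjusted p = 3.18e-06 with an estimated correlation), and of 21 PPARgamma targets 11 fell and 1 rose, 13 and 1 adjusted over the list alone (adjusted p = 1.55e-18, and adjusted p = 0.00233 with an estimated correlation). Interferon genes were higher as a list, 1 of 16 over all genes and 4 adjusted over the list alone (adjusted p = 0.000624), a call lost under the other correlation (adjusted p = 0.146 with an estimated correlation). The myofibroblast list was higher by the test (adjusted p = 0.0432, adjusted p = 0.325 with an estimated correlation) with a mean just below 0 and 0 members called. edgeR called 347 (62 higher and 285 lower) genes, 263 for all-trans retinoic acid alone and 98 for 9-cis-retinoic acid alone, where the neutrophil share was 0% to 1.94%. Without replicate 3 the count was 134, without replicate 2 169 and without replicate 1 265. With DESeq2 size factors the median of all genes moved by 0.29 and 262 (106 higher and 156 lower) genes were called, 40.5% of them higher in place of 17.9%.

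The glucocorticoids corticosterone and dexamethasone sodium phosphate raised known glucocorticoid receptor targets above cells that had already met dexamethasone in the induction mix. Fkbp5, a chaperone of that receptor, rose by 4.39 ± 0.36 (SE) on the log2 scale, from 20.2 ± 13 CPM (SD, n = 25) to 259 ± 116 (n = 8). Tsc22d3 (3.26 ± 0.23), Pdk4 (3.07 ± 0.47), the metallothioneins Mt1 (1.51 ± 0.24) and Mt2 (1.77 ± 0.29), and Clca1 (4.06 ± 0.30) rose too. The contractile genes Tpm1 (-2.25 ± 0.26) and Acta2 (-2.34 ± 0.30) fell, and the chemokine Cxcl1 had no count in the 8 libraries and was at least 15.9-fold lower. Of 10 receptor targets 7 rose over all genes and 9 when adjusted over the list alone (adjusted p = 3.7e-18, and adjusted p = 4.8e-09 with an estimated correlation). Of 9 myofibroblast genes 7 fell under both adjustments, over all genes and adjusted over the list alone (adjusted p = 1.15e-06, and adjusted p = 0.00664 with an estimated correlation). Of 19 matrix genes 10 fell, and 10 fell and 1 rose adjusted over the list alone (adjusted p = 2.27e-08), a call lost under the other correlation (adjusted p = 0.0862 with an estimated correlation). Of 23 fat cell genes 8 fell, and 13 adjusted over the list alone (adjusted p = 6.09e-07, adjusted p = 0.295 with an estimated correlation), with Adipoq at -1.91 ± 0.37 and without the plate term at -0.53, adjusted p = 0.509. edgeR called 689 (385 higher and 304 lower) genes, 294 for dexamethasone sodium phosphate alone and 438 for corticosterone alone, and 438 without replicate 1 of both. Their libraries lay on plate 5, with neutrophil shares of 0.00764% to 0.237% and 0.0162% to 0.784%. Scaling by DESeq2 size factors moved the median of all genes by 0.19, and 67.5% of the calls were higher in place of 55.9%.

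Sodium arsenite raised the oxidative stress gene Hmox1 by 1.79 ± 0.33 (SE) on the log2 scale, to 574 ± 894 CPM (SD, n = 4) from 118 ± 59 (n = 25). The glutathione transferase Gstm1 rose by 1.11 ± 0.27, and the selenoprotein Sepw1 had no count in the 4 libraries and was at least 6.09-fold lower. Of 24 NRF2 targets these 2 rose under both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.000178, adjusted p = 0.247 with an estimated correlation). Fat cell genes were lower as a list, 0 of 23 over all genes and 5 adjusted over the list alone (adjusted p = 3.76e-14, adjusted p = 0.0829 with an estimated correlation). edgeR called 3 (2 higher and 1 lower) genes, with 434 at an unadjusted p under 0.05, and DESeq2 11, of which 1 (Gstm1) was among those 3. Replicate 4 held the Hmox1 rise, which without it stood at 0.91, adjusted p = 0.788, and Gstm1 and Sepw1 were not called without replicate 2 (1.09, adjusted p = 0.841 for Gstm1 and adjusted p = 1 for Sepw1). The count was 1 without replicate 2, 1 without replicate 3 and 7 without replicate 4. Under DESeq2 size factors the median of all genes moved by 0.18 and 5 (4 higher and 1 lower) genes were called, 80% of them higher in place of 66.7%.

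PCB 126, a dioxin-like biphenyl, raised the dioxin receptor target Cyp1b1 by 1.26 ± 0.30 (SE) on the log2 scale, from 131 ± 59.1 CPM (SD, n = 25) to 368 ± 149 (n = 3). The dipeptidase Dpep1 rose by 1.64 ± 0.33 and Plac8 by 1.41 ± 0.34. Of 5 dioxin receptor targets 1 rose under both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.00649, adjusted p = 0.0578 with an estimated correlation). Fabp4 (-0.14 ± 0.52) and Adipoq (-0.06 ± 0.48) did not pass (adjusted p = 1 for both). edgeR called 3 (3 higher and 0 lower) genes, with 243 at an unadjusted p under 0.05, and DESeq2 called 1, which did not include Cyp1b1 (1.25, adjusted p = 1). None of the 3 was called without replicate 1 (Cyp1b1 0.76, adjusted p = 1, Dpep1 1.60, adjusted p = 0.563, Plac8 1.52, adjusted p = 0.563), and 0, 0 and 2 genes were called by edgeR without replicates 1, 2 and 3, with 347 and 230 at an unadjusted p under 0.05 in the first 2 fits.

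**Figure D3:**
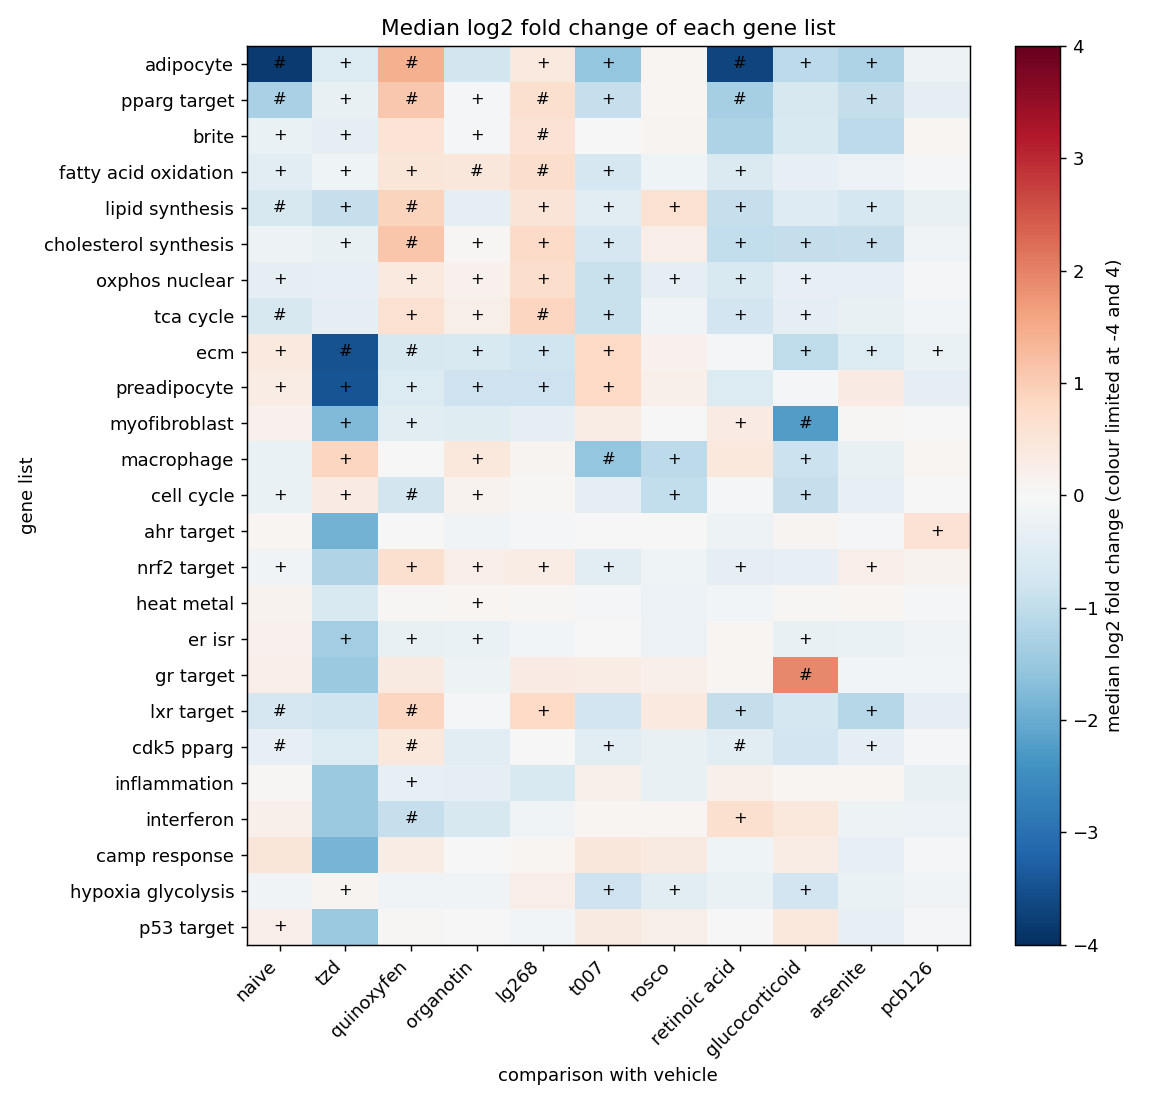
Median log2 fold change against vehicle of each gene list (vertical axis) in 11 comparisons (horizontal axis), with the colour limited at -4 and 4; a plus marks lists called with the preset correlation and a hash those called with an estimated one as well. The test compares a list with the other genes, so a mark can stand on a median of the other sign, and DESeq2 size factors would move the columns of the thiazolidinediones, T0070907 and roscovitine up by 0.71, 0.93 and 0.95.

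Related molecules were compared with each other, at doses that were not given in the sources used here. The retinoid X receptor ligands LG100754 and LG100268 differed widely: Cyp26b1 was higher in LG100754 by 5.81 ± 1.05 (SE) on the log2 scale and Igfbp6 by 7.19 ± 1.20, and Cd36 (-5.49 ± 0.79), Adipoq (-4.38 ± 0.70) and Fabp4 (-4.52 ± 0.74) were lower, with 63 genes higher and 155 lower (n = 3 each). LG100754 lay on plate 5 with a neutrophil share of 0.0669% to 2.9%. LG100268 had no library on that plate, so chemical and plate are separated in this pair only through the plate term. Dibutyltin was below tributyltin in Agt (-3.47 ± 0.60), a difference of -3.08, adjusted p = 0.133 without replicate 1 of both, and 2 genes were higher and 15 lower (n = 3 and 2). Triphenyltin differed from tributyltin in Inmt (-5.18 ± 1.16), the 1 gene called (n = 3 and 2), while Angptl4 did not differ past the test, at -0.08 [-0.95, 0.79] (95% interval). The stereoisomers 9-cis and all-trans retinoic acid differed in Igfbp6 (2.65 ± 0.56), the 1 gene called (n = 4 and 3), and Fabp4 stood at 1.48 [0.13, 2.84] (adjusted p = 0.598). Telmisartan exceeded candesartan in Tsc22d3 (3.06 ± 0.46) and fell below it in Sncg (-4.72 ± 0.73), with 17 genes higher and 11 lower (n = 4 and 3, plate 5).

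Among the phthalates, the monoester mono(2-ethylhexyl) phthalate exceeded its diester di(2-ethylhexyl) phthalate in Agt (2.63 ± 0.57) and Clca1 (2.76 ± 0.64), with 3 genes higher and 2 lower (n = 3 and 2), and the brominated mono-(2-ethyhexyl) tetrabromophthalate was below it in Agt (-2.53 ± 0.47), Dpep1 (-2.97 ± 0.50) and Fkbp5 (-2.60 ± 0.59), with 1 gene higher and 8 lower (n = 3 each). The well position of mono(2-ethylhexyl) phthalate is given in the closing section. Honokiol and its isomer magnolol differed in 434 genes higher and 476 lower (n = 2 and 3), but the difference in the histone gene Hist1h1b (-5.88 ± 1.06) turned to 0.25, adjusted p = 1 without replicate 2 of both. Troglitazone against rosiglitazone called 5 genes higher and 216 lower at the low totals and the neutrophil share of troglitazone given above, with a median log2 fold change of all genes of -1.33. Troglitazone and rosiglitazone shared no plate, so that contrast rests on the plate term. Of the 22 pairs 13 had 0 genes called by edgeR, with 176 to 504 genes at an unadjusted p under 0.05, and DESeq2 called 0 in those 13. For these the 95% intervals of Fabp4 were wide: 1.09 [-0.26, 2.43] for bisphenol S against bisphenol A, -0.23 [-1.76, 1.30] for the fluorinated acids PFOS against PFOA and -0.81 [-2.18, 0.55] for DDE against DDT.

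Across the 75 chemicals tested against vehicle one by one, fat cell genes moved as a list in 50, higher in 40 and lower in 10. With an estimated correlation the list was higher in 8 (Firemaster 550, nTZDpa, quinoxyfen, S26948, SR1664, Tonalid, rosiglitazone and allethrin) and lower in 3 (both retinoic acids and LG100754). Matrix genes were lower in 38 and higher in 3, and lower in 8 with an estimated correlation. Brite fat genes were higher in 13 and, with an estimated correlation, in 4, namely nTZDpa, S26948, triphenyltin and rosiglitazone. Dioxin receptor targets were higher in 1 chemical, PCB 126, and in 0 with an estimated correlation. Firemaster 550, a flame retardant mixture, raised Cidec (3.05 ± 0.54), Cox8b (2.96 ± 0.57) and Fabp4 (2.07 ± 0.52, n = 3), of 138 genes called. Without replicate 2 edgeR called 0 (602 at an unadjusted p under 0.05, with DESeq2 not run there), with Cidec at 2.80, adjusted p = 0.0649, Cox8b at 2.98, adjusted p = 0.0648 and Fabp4 at 1.87, adjusted p = 0.302, and without the plate term Cidec stood at 0.34, adjusted p = 0.971. nTZDpa raised Cox8b (2.90 ± 0.56) and Cidec (2.44 ± 0.53, n = 3), 27 genes in all and 1 without replicate 1, when Cox8b stood at 2.62, adjusted p = 0.0952 and Cidec at 2.26, adjusted p = 0.269.

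At least 20 genes were called in 29 chemicals, 1 to 19 in 13 and 0 in 33, by the edgeR test. The 33 with 0 had 143 to 694 genes at an unadjusted p under 0.05, and DESeq2 called 0 in 32 of them and 1 in the other. Of 100 draws each of 2, 3 and 4 vehicle libraries treated as a chemical, 15, 14 and 8 had at least 1 gene called and 4, 3 and 1 at least 20, with at most 68, 103 and 30 genes. After T0070907 and roscovitine, resolvin-E1 had the most calls of a single chemical (781 genes, 0 by edgeR without the well block of plate 5, 290 at an unadjusted p under 0.05), followed by magnolol (737, 65 without replicate 2) and telmisartan (578). Of the chemicals with 3 libraries and at least 20 genes, 4 had 0 by edgeR without 1 replicate (DESeq2 was not run there): Firemaster 550, given above, and cyazofamid, DDT and candesartan. Without replicates 1, 2 and 3 it was 0, 30 and 57 for cyazofamid (32 with all, and 599 genes at an unadjusted p under 0.05 where it was 0), where Mt2 went from 2.86 ± 0.39 to 0.68, adjusted p = 0.814. For DDT it was 73, 0 and 56 (39 with all, 291 unadjusted), with Oas2 from 3.50 ± 0.66 to 0.49, adjusted p = 1, and for candesartan 0, 12 and 54 (42 with all, 738 unadjusted), with Enpp2 from 2.36 ± 0.43 to 1.28, adjusted p = 0.628.

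**Figure D4:**
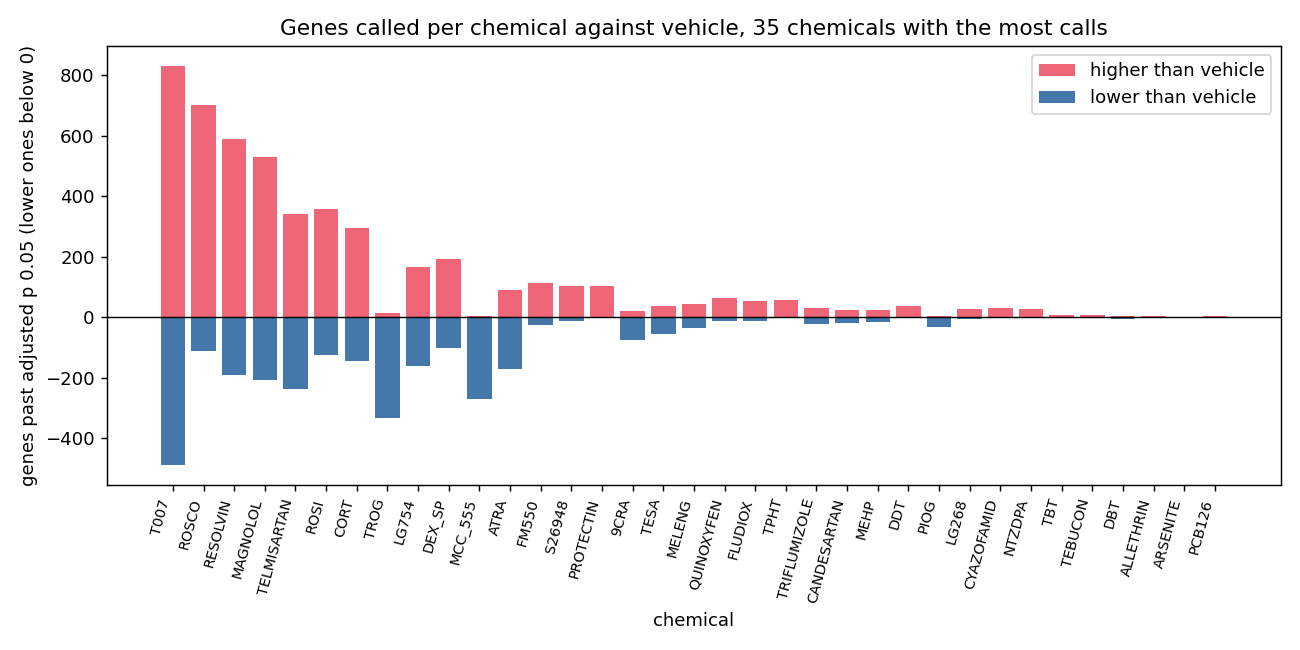
Genes called against vehicle per chemical for the 35 chemicals with the most calls, those higher above 0 and those lower below 0. T0070907 led with 831 higher and 487 lower genes; 226 were called without replicate 1 (210 of them among the first 1318), 145 without replicate 2 (139 among them), and 0 by edgeR without the well block of plate 5 (648 at an unadjusted p under 0.05).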

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

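In this part the test of neutrophil counts against library depth, the comparison of near-identical libraries, and the fits without plate 6, without the well block, with pairs of libraries left out and with splits within plates were chosen after the results were seen. Values per library below are CPM. Of 195 sets of 4 to 10 libraries 22 (11.3%) had a library far from the others. Whether this share exceeds chance cannot be told, because a library with the only counts of a gene is flagged however few they are.

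In T0070907, replicate 3 stood apart in neutrophil and myeloid genes: S100a8 371 against 32.3 to 87.9, Camp 239 against 42.6 to 64.8 and Lyz2 58.5 against 7.69 to 16.1 in the other 3 libraries. Replicate 4 stood apart in the apolipoprotein gene: Apoc1 150.5 against 83.9 to 86.4. In corticosterone, replicate 4 was low in receptor targets (Fkbp5 127 against 304 to 331, Tsc22d3 429 against 1669 to 1917, Mt1 3540 against 8749 to 9206) and held the chemokine Cxcl5 31.8 against 0. Replicate 1 held Cox6a2 7.31 against 0 and Gpr81 1.83 against 0, and replicate 3 Ces1a 6.25 against 0 and Tagln 18.7 against 0. In dexamethasone sodium phosphate, replicate 1 held Adipoq 3302 against 1131 to 1352, Tshr 2.28 against 0 and Myl9 6.84 against 0, and replicate 4 Mfap4 28.3 against 0 to 4.56. In arsenite, replicate 4 held Hmox1 1913 against 62.3 to 167. Single libraries also stood apart in 9-cis-retinoic acid (replicate 3 Aldh1a7 2.54 against 0, replicate 2 Plin1 6.21 against 0), roscovitine (replicate 4 Procr 7.42 against 0 to 1.14), resolvin-E1 (replicate 1 Elovl3 0.288 against 0) and telmisartan (replicate 1 Slc1a5 587 against 161 to 223). Several of these are a few counts set against none.

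The chemical with 1 library, the liver X receptor agonist T0901317, lay outside the tests. In that library (298771 counts, plate 2) 8 of 12 liver X receptor targets exceeded the 6 vehicle libraries of the plate: among them Abca1 66.9 against at most 24.4, Mylip 117 against at most 49.2, Lpcat3 130.5 against at most 70.6, Apoe 97.1 against at most 16.8, Scd1 2554 against at most 396 and Scd2 489 against at most 268. Abcg1 and Smpdl3a had no count in it or in those vehicle libraries and were left out of the median log2 ratio, which over the other 10 was 1.45 with 5 CPM added, above each of 10000 random lists matched on expression. This describes that library, and with 1 library no test across replicates was possible. The random lists also take no account of list members that move together. Over the vehicle libraries of all plates Scd1 varied widely, at 741 ± 1797 TMM-scaled CPM (SD, n = 25).

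The first pattern was the fall of 1415 genes under the thiazolidinedione class, where 13 rose. Neutrophil transcripts on plate 6, which held the troglitazone and MCC-555 libraries, might carry part of it: without plate 6 243 genes fell. That fit kept pioglitazone, on plate 5 with a neutrophil share of up to 5.8%, so it did not remove all neutrophil counts. Low totals might carry the fall too, since in rosiglitazone, with deep libraries, the median log2 fold change over the genes that fell was -0.425, which lay between the bounds set for and against. A fixed amount of neutrophil RNA per well was tested through depth: on plate 6 (17 libraries) neutrophil counts rose with the remaining counts, with a Spearman correlation of 0.64 (permutation p = 0.00709, adjusted 0.0142) and a Pearson correlation of 0.543 (permutation p = 0.0226, adjusted 0.0452; 0.424 without the 2 farthest libraries), and on plate 5 (72 libraries) the values were 0.0428 (permutation p = 0.72, adjusted 0.72) and 0.00408 (permutation p = 0.973, adjusted 0.973; -0.0435 without 2). None of the 3 was excluded for the class as a whole, and they cannot be told apart because most shallow libraries of the class lay on plate 6. The falls of Dcn, Postn and Col3a1 held without plate 6 and without the shallow libraries. The former fit kept the pioglitazone libraries, and the latter left rosiglitazone as the only member. An effect of the drugs stays open.

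The second pattern was the rise of 831 genes under T0070907 and 701 under roscovitine. A block of 8 wells of plate 5, which held replicates 1 and 2 of both, may lie behind it: without these wells 0 and 0 of the genes were still called as rising by edgeR, with 648 and 604 genes of any direction at an unadjusted p under 0.05 (DESeq2 was not run without the block). The median log2 fold change over these genes went from 1.22 to 0.33 (quartiles 0.0181 and 0.68) under T0070907 and from 1.40 to 0.12 (quartiles -0.37 and 0.56) under roscovitine without the block, and over the genes that fell from -1.33 to -0.75 and from -1.38 to -0.67. The values argue against the loss of 2 libraries as the whole cause: without replicates 1 and 2 the rises kept 28.6% and 5.26% of their median, against 46.7% to 127% over each pair left out of 4 chemicals outside the block with 4 libraries and at least 20 rises (9-cis-retinoic acid, corticosterone, dexamethasone sodium phosphate and telmisartan). Of the genes that rose, 434 were shared by T0070907 and roscovitine, against 65.2 if independent. With resolvin-E1, also in the block, roscovitine shared 388 (46.2 if independent), and with corticosterone, outside it, 65 (23.1 if independent). All these comparisons share the vehicle libraries, so their calls are not independent and the values if independent are not a chance level. An effect of the chemicals on part of the genes stays open.

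The third pattern was the closeness of replicates 1 and 2 on plate 5. Their chi-square per degree of freedom was 1.15 in resolvin-E1 (totals 2273159 and 2273411), 1.14 in roscovitine and 1.29 in T0070907, while the closest other pair of these chemicals reached 1.72, so that 1 RNA or culture may lie behind both libraries of a pair. A value of 1 would be sampling noise, which is more easily reached at low totals. A corticosterone pair outside the block, with totals (629221 and 531745) near those of the roscovitine pair (453105 and 577681), stood at 1.21. Vehicle replicates 15 and 16 stood at 1.12 over 5607 genes and naive replicates 3 and 4 at 1.21 over 5773. Replicates 1 and 2 of LG100754, also on plate 5, stood at 1.31 over 6439 genes. Close pairs thus occurred outside the block too, so closeness does not decide whether 1 RNA or culture was shared. The libraries were kept as separate, and no biological explanation was tested.

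Each count of called genes was set against 100 other splits of the same libraries in a fit of the compared groups alone, drawn first over all plates and then by trading libraries only within a plate, since several groups lay on 1 plate. For 6 comparisons 1 of 101 splits, the real one, gave as many genes in both draws. That is the lowest share these draws can give, and it was not corrected for 13 comparisons. It also covers the counts of this fit and not those of the main fit, so these draws did not clearly exclude chance. For naive cells, with 608 genes against at most 9 and 137 in the other splits, the values argue against chance. The real count, the highest other over all plates and the highest other within plates were 608, 9 and 137 for naive cells; 59, 23 and 2 for the organotins; 188, 166 and 10 for LG100268; 516, 19 and 353 for the retinoic acids; 549, 34 and 277 for the glucocorticoids; 251, 20 and 18 for quinoxyfen. T0070907, all on plate 5, had 1 of 101 over all plates (792 real, 13 the highest other) but 15 of 101 within plates (2118 the highest), and roscovitine 3 (133 and 2541) and 35 (2490), so chance was not excluded for their counts. Splits with several times the real count point to a structure of the libraries, and the 2541 genes for roscovitine came from its replicates 1 and 2, from the well block, grouped with 2 vehicle libraries.

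For the thiazolidinediones 1 of 101 splits over all plates (1264 real, 120 the highest other) and 2 of 101 within plates (1309) gave as many, and for the organotins against them 1 of 101 (485 and 257) and 1 of 24 (292), shares under 0.05 that were not corrected for 13 comparisons. For quinoxyfen against them 3 of 101 gave as many (201 and 259), and within plates the 2 splits were too few for a share under 0.05 (1 gave as many, 125 for the other). For arsenite 6 of 101 over all plates (6 and 146) and 2 of 101 within plates (21) gave as many, so chance was not excluded by the first. For PCB 126 the values were 3 of 101 (5 and 49) and 1 of 101 (2), but 14 of 100 draws of 3 vehicle libraries had at least 1 gene called and the highest 103, so it was not clearly excluded either.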

How the results depend on the processing

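The fits without plate 6, without the well block and with the block alone were chosen after the data were seen. No paired analysis was possible because the labels give no replicate numbers. Of 6218 values of named genes under an alternative, 5315 kept their direction and their call, 875 kept their direction and lost the call and 28 changed direction. The cause was not tested unless stated. Counts that moved by more than 1.5 times follow, and those not given here stayed within that range. The main counts were 414 for naive cells, 1428 for thiazolidinediones, 1318 for T0070907, 18 for organotins, 34 for LG100268, 347 for retinoic acids, 813 for roscovitine, 689 for glucocorticoids, 3 for arsenite, 3 for PCB 126, 75 for quinoxyfen, 693 for organotins against thiazolidinediones, 778 for quinoxyfen against thiazolidinediones, 5 related pairs with at least 10 genes, 29 chemicals of the screen with at least 20 genes, and 133 of 325 list tests.

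With DESeq2 size factors the counts were thiazolidinediones 339, T0070907 4712, LG100268 57, roscovitine 4302, arsenite 5, organotins against thiazolidinediones 158 and quinoxyfen against thiazolidinediones 107, and with the DESeq2 Wald test thiazolidinediones 367, T0070907 4659, organotins 48, LG100268 106, roscovitine 4298, arsenite 11, PCB 126 1, organotins against thiazolidinediones 215 and quinoxyfen against thiazolidinediones 125. Without a filter they were organotins 34, arsenite 15, PCB 126 5 and quinoxyfen 147, and with the stricter filter roscovitine 1254. Without the plate term they were T0070907 790, organotins 8, LG100268 17, roscovitine 1298, glucocorticoids 1338, arsenite 1, quinoxyfen 15 and organotins against thiazolidinediones 1126. With only the groups compared, which re-estimates the spread from fewer libraries, they were T0070907 792, organotins 59, LG100268 188, roscovitine 133, arsenite 6, PCB 126 5, quinoxyfen 251 and quinoxyfen against thiazolidinediones 201. Within single plates, with fewer libraries, naive cells gave 38, 178, 225 and 30 on plates 1, 2, 4 and 5. Without the shallow libraries, which left rosiglitazone as the only thiazolidinedione, the counts were thiazolidinediones 545, organotins against thiazolidinediones 253 and quinoxyfen against thiazolidinediones 18, and without plate 6 thiazolidinediones 363, organotins against thiazolidinediones 70 and quinoxyfen against thiazolidinediones 31. Without the well block they were T0070907 0, organotins 30, LG100268 57, roscovitine 0, quinoxyfen 131 and quinoxyfen against thiazolidinediones 1190, and with only the block for those 2 chemicals T0070907 3689 and roscovitine 3543. Of 325 list tests 31 were called with an estimated correlation, 84 with the directional and 4 with the mixed form of fry.

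For classes, leaving out 1 chemical gave the thiazolidinediones 742 genes without troglitazone and 749 without MCC-555, the organotins 11 without tributyltin, 63 without dibutyltin and 5 without triphenyltin, the retinoic acids 98 without the all-trans form, and the glucocorticoids 294 without corticosterone and 438 without dexamethasone sodium phosphate. Leaving out each replicate in turn, with fewer libraries, gave 467 to 603 for thiazolidinediones, 145 to 2839 for T0070907, 6 to 10 for organotins, 7 to 28 for LG100268, 134 to 290 for retinoic acids, 9 to 2075 for roscovitine, 438 to 584 for glucocorticoids, 1 to 7 for arsenite, 0 to 2 for PCB 126, 20 to 64 for quinoxyfen, 119 to 818 for organotins against thiazolidinediones, 127 to 592 for quinoxyfen against thiazolidinediones, 2 to 5 for related pairs, 18 to 30 for the screen. Where the count was 0, for PCB 126 without replicate 1 or 2, edgeR had 347 and 230 genes at an unadjusted p under 0.05, and DESeq2 called 1 in the full data.

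Some log2 fold changes turned to the other side of 0. Without shallow libraries the value was for thiazolidinediones Mt1 0.021, for organotins against thiazolidinediones Angptl4 -0.70 and Mt1 -0.0118 and for quinoxyfen against thiazolidinediones Angptl4 -1.18 and Lpl -0.39. Without the well block of plate 5 the value was for roscovitine Tanc2 -0.43, for protectin D1 Sh3pxd2a -0.45, for resolvin-E1 Ttc28 -0.33 and for roscovitine as a single chemical Sh3pxd2a -0.32. Without the plate term the value was for quinoxyfen Cidec -0.36, for nTZDpa Cidec -0.24 and for triphenyltin Cidec -0.051. Without plate 6 the value was for organotins against thiazolidinediones Angptl4 -0.22 and for quinoxyfen against thiazolidinediones Angptl4 -0.64. Over the replicates left out in turn (the replicate whose absence turned the sign in parentheses), values ran as follows, for thiazolidinediones Tuba4a -0.17 to 1.41 (1), for organotins against thiazolidinediones Slc1a5 -2.03 to 0.60 (2), for magnolol Cidec -0.86 to 2.31 (1), Cd36 -1.73 to 2.03 (1), Tk1 -0.13 to 5.73 (2), Birc5 -0.36 to 4.58 (2), Hist1h1b -0.61 to 5.47 (2) and Fkbp5 -0.50 to 2.27 (2), for tesaglitazar Glb1 -0.17 to 3.81 (1) and for honokiol against magnolol Pparg -3.19 to 0.74 (1), Cd36 -3.00 to 0.61 (1), Hist1h1b -7.05 to 0.25 (2) and Ckap2l -6.21 to 1.14 (2). The cause was not tested.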

Other observations

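The tests of single chemicals in this part were planned, and the choice of which to describe was made after their values were seen. Telmisartan, a blood pressure drug (plate 5, neutrophil share 0.00441% to 1.27%), raised glucocorticoid receptor targets: Fkbp5 rose by 3.97 ± 0.41 (SE, n = 4) on the log2 scale and Pdk4 by 3.15 ± 0.52, with Agt at 3.68 ± 0.31 and Ptgds at 4.40 ± 0.53. Melengestrol acetate, a steroid progestin, raised Fkbp5 (3.24 ± 0.38, n = 3), Tsc22d3 (2.54 ± 0.29), Clca1 (3.01 ± 0.32) and Dpep1 (2.89 ± 0.31). In mono(2-ethylhexyl) phthalate Fkbp5 (3.01 ± 0.39, n = 3), Clca1 (2.69 ± 0.34), Agt (2.85 ± 0.34) and Dpep1 (2.45 ± 0.33) were higher. On the plates they shared, its wells lay next to those of melengestrol acetate. Monobenzyl phthalate, in the wells after it, stood at 1.98 ± 0.50 for Fkbp5 (adjusted p = 0.239). Whether well position played a part was not tested. The receptor target list was higher with an estimated correlation in 6 chemicals, these 3, corticosterone, dexamethasone sodium phosphate and monobenzyl phthalate, and myofibroblast genes were lower in 4, telmisartan, melengestrol acetate, corticosterone and dexamethasone sodium phosphate. No biological explanation was tested.

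S26948, a PPARgamma ligand, raised Fabp3 by 6.61 ± 1.01 (SE, n = 2), Cox7a1 by 4.77 ± 0.64 and Ephx2 by 3.53 ± 0.46, and triphenyltin raised Agt (2.71 ± 0.34, n = 3), Angptl4 (2.26 ± 0.30) and Ephx2 (3.01 ± 0.39). In LG100754, a retinoid X receptor ligand on plate 5 with a neutrophil share of 0.0669% to 2.9%, Inmt rose by 6.93 ± 0.48, Igfbp6 by 6.22 ± 0.46 and Cyp26b1 by 6.63 ± 0.75, and Adipoq fell (-4.10 ± 0.54, n = 3). Magnolol raised the division genes Tk1 (4.25 ± 0.42) and Birc5 (3.65 ± 0.41, n = 3), which without replicate 2 stood at -0.13, adjusted p = 0.994 and -0.36, adjusted p = 0.937. Cell cycle genes were higher with an estimated correlation in 2 chemicals, magnolol and triphenylphosphine oxide. With that correlation interferon genes were lower in 1, quinoxyfen, and higher in 3, all-trans retinoic acid, DDT and pregnenolone 16alpha-carbonitrile. Triphenylphosphine oxide and pregnenolone 16alpha-carbonitrile had 0 single genes by edgeR and DESeq2 (359 and 187 at an unadjusted p under 0.05). In DDT without replicate 2 Oas2 stood at 0.49, adjusted p = 1 and Mx2 at 1.09, adjusted p = 1, and edgeR called 0 genes (291 at an unadjusted p under 0.05, with DESeq2 not run there).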
